A study of Mus musculus with 8 samples.

How the data were processed

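The series holds 8 mouse samples of total RNA: MEFs with a conditional TRF2 allele, induced or uninduced and sequenced by TEsR, MES cells sequenced by TEsR, and induced MEFs sequenced by TruSeq, with 2 samples per group. Per the labels' protocols, RNA was isolated with a small RNA kit, ribosomal RNA was removed before TEsR capture, and TEsR uses linker ligation, cap removal, amplification and hybridisation capture without size selection. The deposited values are whole-number read counts per annotated small RNA, with no normalization by the authors, in 2 tables of 5518 rows with the same rows, per the file headers. Per the submitters' processing notes, cutadapt, BWA 0.7.12, SAMtools 1.2.1 and bedtools 2.25.0 were used with mm10; the role of each tool, the settings and the strand use in counting are not given in the sources used here. The deposited column names of the TEsR table hold the tag q10, whose meaning is not stated. Reads carried no molecular identifiers, so all intervals and limits given cover counting error only.

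Columns were assigned by name. The MES columns name the cell and replicate. The TruSeq columns carry an index and no replicate number, so they are named by index and stand for their group. The name of the TruSeq table calls it a control while the sample titles say induced; groups follow the titles. The names of 4 TEsR columns of MEFs carry codes that the labels do not explain, so that induced and uninduced could not be told apart, and these 4 columns were used in no step. The comparisons planned before the data were examined (induced against uninduced MEFs, MES against either, and TEsR against TruSeq in induced MEFs) were therefore not made, nor were their list tests. Class shares and features detected, planned at the same time, were computed on 4 libraries. The comparison of MES by TEsR with induced MEFs by TruSeq was added after seeing the data, with the tests and alternatives planned for the others.

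Each row was given the gene type of GENCODE vM21 (mm10 coordinates) through its Ensembl identifier. Of the 5518 rows, 5453 were in the annotation, 5445 of them at the same coordinates, and the 65 others had 0 counts. The rows were 2207 miRNAs, 1507 snoRNAs, 1384 snRNAs, 354 rRNAs and 1 unassigned transcript, and 784 had a count in any of the 4 libraries. Overlapping rows were counted more than once by the authors: of 43 overlapping pairs with counts, 30 had identical counts in every library, and these duplicates made up 0.891% to 1.51% of a library. The miRNA lists use rows that overlap no snoRNA or rRNA row, with duplicates counted once and AC161199.1 left out. Of the miRNA rows left out for such an overlap, 14 had counts. Host genes and introns come from the same annotation, on the same strand.

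Shares were computed over all counts of a library, with exact Clopper-Pearson 95% binomial intervals for single libraries and 3 counts as the limit for a count of 0. Detection was counted at minimums of 1 and 10, as deposited and after thinning each library to 2676776 counts by multivariate hypergeometric draws with a fixed seed. Replicates differed by more than sampling noise (chi-square per degree of freedom 19.3 for MES and 511 for TruSeq), so no library was counted as a duplicate; the Pearson correlation of log2 CPM across rows, which are not independent replicates, was 0.994 and 0.970.

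The comparison of 2 MES with 2 TruSeq libraries used edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, robust, trimmed mean of M-values scaling, filterByExpr with a minimum count of 10) with Benjamini-Hochberg adjustment and a threshold of 0.05. Of 352 rows tested, 306 had an unadjusted p under 0.05. Lists with at least 3 tested members were tested with limma 3.58.1 (camera with a correlation of 0.01 and a prior count of 2, and fry), adjusted over the lists. On counts simulated for this comparison over 352 rows, of which 340 were tested and 176 changed, 95.2% of 4-fold and 100% of 16-fold changes were called with the right sign, and 2 of 168 unchanged rows were called. The simulation gave all 4 libraries one mean profile and one trend of spread, with changes balanced in direction. It lacked the unequal replicate spread and the group-specific dominant rows of the data, so it does not measure false calls in them. CPM are counts relative to the library's total, without the scaling factors. Fold bounds are mean CPM over the limit of 3 counts. They leave out the scaling that the calls use, which would make bounds smaller for rows lower in MES and larger for rows higher in MES. Alternatives were DESeq2 1.42.0 (size factors and Wald test), library size only, no filter, each library left out, rows summed by name, miRNAs only, and duplicates counted once.

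The 21 lists of RNAs and the rule for named RNAs were fixed before the data were examined. The rule took, among called rows with a mean of at least 10 CPM in the higher group and no overlap between groups, the 8 largest changes in each direction, up to 4 called members of each list with the largest changes, and the 3 rows with the highest share in each class. Members and rows named beside these were chosen after their values were seen. The 10000 random lists of the closing section were drawn with a fixed seed, and permutation tests used 100000 resamples. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.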

Results

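Small RNAs were counted in mouse embryonic stem (MES) cells by target-enrichment sequencing of small RNAs (TEsR), in which linker-ligated RNAs are amplified, captured by hybridisation to probes and sequenced on a MiSeq. They were also counted in mouse embryonic fibroblasts (MEFs) by standard TruSeq small RNA sequencing on a HiSeq. The fibroblasts carried a conditional allele of TRF2, a protein that caps telomeres, and their titles call them induced, meaning deletion of TRF2 through a tamoxifen-activated Cre with 0.6 µM 4-hydroxytamoxifen for 48 hours. Of the 8 samples of the series, 4 libraries in 2 groups of 2 are reported: MES replicates 1 and 2, with 2785150 and 2676776 counts over annotated small RNAs, and the TruSeq libraries carrying the indexes ATCACG and CGATGT, with 8961221 and 8442960 counts. The labels do not say that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Coordinates are on mm10.

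The study set the capture method beside standard small RNA sequencing, and the class makeup of the counts is given first. Cells and induction also differ between the groups used here, so these shares do not read the methods alone. Small nucleolar RNAs (snoRNAs), guides of ribosomal RNA modification, took 99.7% ± 0.00152 (SD, n = 2) of the counts in the MES libraries and 74.5% ± 1.97 (SD, n = 2) in the TruSeq libraries. Rows annotated as microRNA (miRNA) took 0.315% ± 0.0026 (SD, n = 2) in MES and 22.9% ± 2.02 (SD, n = 2) in TruSeq. The spliceosomal and other small nuclear RNAs (snRNAs) took 0.00274% ± 0.000648 (SD, n = 2) in MES and 0.685% ± 0.0567 (SD, n = 2) in TruSeq. No MES library had a count on a ribosomal RNA row, which allows shares of up to 1.08e-04% and 1.12e-04%, while the TruSeq libraries had 0.00215% ± 0.000245 (SD, n = 2). Per the labels' protocols, ribosomal RNA had been removed before TEsR capture. Each of these differences between the groups was larger than the spread within either group, but the exact permutation test of 2 against 2 libraries cannot go below a two-sided p of 0.333.

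**Figure D1:**
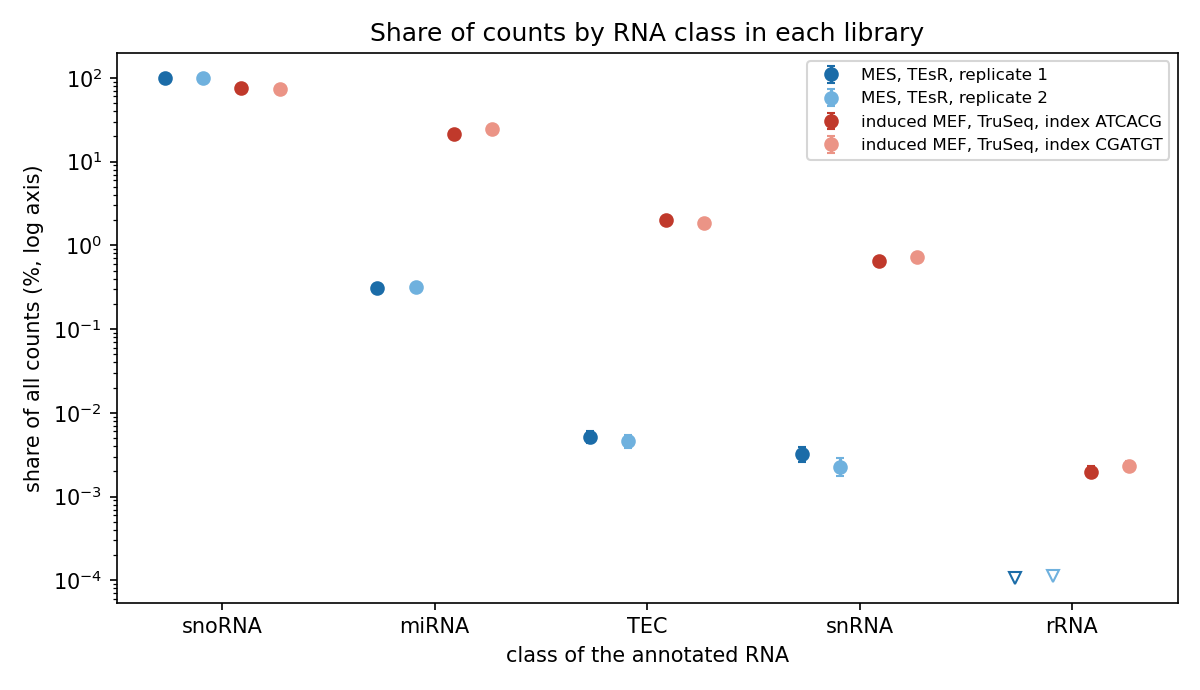
Share of all counts (%, log axis) taken by each class of annotated RNA in each library, with exact 95% binomial intervals that cover counting error only; open triangles mark the upper limit that a count of 0 allows. The snoRNA points lie at 99.7% in MES and at 75.8% and 73.1% in TruSeq, and TEC is the annotation's class for an unassigned transcript with 1 row, Gm22574.

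A few snoRNAs made up most of each library, and they were different ones in each group. In MES, Snord68 (chr 8, 123103038 to 123103123, in an exon of at least 1 transcript of Rpl13) held 53.8% ± 1.03 (SD, n = 2) of the counts and Snord70 (chr 1, 59691934 to 59692020, in an intron of Nop58) 27.9% ± 0.0306 (SD, n = 2). Gm26293, another snoRNA of Nop58, followed with 4.70% ± 0.138 (SD, n = 2). In TruSeq, Gm23212 (chr 1, 161036682 to 161036741, in Gas5, a snoRNA host gene) held 46.9% ± 4.67 (SD, n = 2). Gm26202, in an intron of Rpl17, held 3.57% ± 0.464 (SD, n = 2) and Gm23246, in Snhg1, another host of snoRNAs, 3.47% ± 1.43 (SD, n = 2).

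The high TruSeq share of the miRNA class came from 1 row. AC161199.1 (chr 15, 80082847 to 80082954, in an intron of Rpl3) is typed as miRNA in the annotation but carries the name Snord43 there, and it held 22.8% ± 2.02 (SD, n = 2) of the TruSeq counts. It made up 99.5% ± 0.0371 (SD, n = 2) of the TruSeq counts of the miRNA class and 4.81% ± 0.0212 (SD, n = 2) of those in MES. With this row counted as snoRNA, an alternative chosen after seeing the data, the miRNA class took 0.110% in TruSeq and 0.300% in MES, so that the order of the groups turned. Below it, mmu-mir-3535, in Ncl, held 0.0281% ± 0.00196 (SD, n = 2) and mmu-mir-677, in an intron of Atp5b, 0.0230% ± 0.0129 (SD, n = 2) in TruSeq. Both rows have the same counts in every library as overlapping rows typed as snoRNA, Gm24148 and Mir677, so these counts cannot be assigned to miRNA. In MES the leading miRNA rows were Mir106b with 0.0678% ± 0.00144 (SD, n = 2), Mir19a with 0.0219% ± 0.000578 (SD, n = 2) and mmu-mir-5121, which overlaps Snord33, with 0.0211% ± 0.000781 (SD, n = 2). The leading snRNA row in TruSeq was Gm25099 with 0.397% ± 0.0298 (SD, n = 2), followed by Gm25313 with 0.0712% ± 0.00895 (SD, n = 2) and Rnu5g, a U5 spliceosomal RNA, with 0.0534% ± 0.00383 (SD, n = 2). In MES the 3 leading snRNA rows were Gm25360, Gm26316 and Gm22710, at means of 10.8, 8.20 and 2.36 counts scaled by library size (CPM). Of the ribosomal RNA rows, Rn18s-rs5 led in TruSeq with 11.7 ± 5.29 (SD, n = 2) CPM, followed by n-R5s2 with 1.62 ± 0.393 (SD, n = 2) and n-R5s115 with 1.47 ± 1.24 (SD, n = 2).

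More small RNAs were seen in the TruSeq libraries than in the MES libraries at one total depth, except among miRNAs. The 2 leading rows held 80.9% and 82.3% of the MES libraries and 71.6% and 67.8% of the TruSeq libraries. At one total, fewer counts were thus left for the other rows in MES. After thinning to 2676776 counts, 211 ± 2.83 (SD, n = 2) rows had at least 10 counts in MES and 273 ± 1.41 (SD, n = 2) in TruSeq. For snoRNAs the numbers were 144 ± 0 (SD, n = 2) and 221.5 ± 0.707 (SD, n = 2), and for snRNAs 2 and 18. For miRNA rows clear of snoRNA and rRNA rows the order was the other way, with 55.5 ± 2.12 (SD, n = 2) in MES and 23.5 ± 2.12 (SD, n = 2) in TruSeq. At the deposited depths both groups had a mean of 55.5 such miRNAs, and 10 of them had at least 10 counts in all 4 libraries. With at least 1 count, 413.5 ± 2.12 (SD, n = 2) rows were seen in MES and 478 ± 31.1 (SD, n = 2) in TruSeq after thinning.

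The MES libraries held the miRNA clusters known from pluripotent cells, miR-290-295 and miR-302-367, and the TruSeq libraries had no count of either. Shares of miRNA counts are given over miRNA rows that overlap no snoRNA or rRNA row, without AC161199.1, a choice made after seeing the data. Overlapping rows with identical counts were counted once, but those with near-equal counts, such as Mir126a and mmu-mir-126b, both stay in. The shares rest on 6730 and 6480 counts in MES and on 5403 and 3366 in TruSeq. The miR-290-295 cluster held 19.4% ± 0.925 (SD, n = 2) in MES, while none of its 7 separate rows had a count in TruSeq, which allows shares of up to 0.0555% and 0.0891%. The miR-302-367 cluster held 1.12% ± 0.266 (SD, n = 2) in MES, with 47 and 65 counts of Mir302a, and had no count in TruSeq. The miR-17-92 cluster and its paralogs, which promote proliferation, held 46.1% ± 1.21 (SD, n = 2) in MES and 30.1% ± 5.55 (SD, n = 2) in TruSeq, through different members. With Mir92-1 left out because its TruSeq counts nearly equal those of its neighbour Mir19b-1, an alternative chosen after seeing the data, the shares were 46.0% ± 1.17 (SD, n = 2) and 19.1% ± 3.56 (SD, n = 2). Mir106b had 1916 and 1787 counts in MES and 40 and 45 in TruSeq, whereas Mir19b-1 had 0 and 1 in MES and 859 and 391 in TruSeq. Mir19b-1 has a further copy, Mir19b-2, and whether reads shared by copies were treated alike in both tables is not stated. The Sfmbt2 intronic cluster, a repeat family whose copies can share reads, held 0.772% ± 0.0222 (SD, n = 2) in MES, mostly on Mir467c, and had no count in TruSeq.

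The let-7 family, which marks differentiated cells, held 6.0% ± 1.97 (SD, n = 2) of these counts in TruSeq and 0.0900% ± 0.0618 (SD, n = 2) in MES, on 9 and 3 counts. The mesenchymal miRNAs held 18.4% ± 0.134 (SD, n = 2) in TruSeq and 8.73% ± 0.383 (SD, n = 2) in MES. Their members went both ways, with Mir214 at 376 and 165 counts in TruSeq against 7 and 10 in MES, and Mir21a at 55 and 75 in TruSeq against 350 and 370 in MES. The p53 and DNA damage miRNAs held 6.24% ± 0.628 (SD, n = 2) in TruSeq, led by Mir143, and 0.468% ± 0.0731 (SD, n = 2) in MES, where Mir34a had 16 and 17 counts. In TruSeq Mir34a had 3 and 5 counts, and Mir143, with 176 and 97, is also on the mesenchymal list. No uninduced MEF library was used, so these shares do not read a response to induction. The senescence and inflammation miRNAs held 7.77% ± 0.422 (SD, n = 2) in MES and 4.54% ± 2.83 (SD, n = 2) in TruSeq, a difference close to the SD of the TruSeq libraries. The miR-200 and miR-183 families held 3.04% ± 0.133 (SD, n = 2) in MES, and 0.333% and 3.59% in the ATCACG and CGATGT libraries. The Dlk1-Dio3 imprinted miRNAs also set these libraries apart, with 78 counts in the ATCACG library and 0 in the CGATGT library, against 2 and 4 in MES. Hox locus miRNAs held 0.0526% ± 0.0307 (SD, n = 2) in MES and 0.454% ± 0.198 (SD, n = 2) in TruSeq. Markers of other tissues were near the floor: muscle miRNAs had at most 1 count in any library, neural miRNAs at most 2, and blood and liver miRNAs 9 and 4 in MES and 0 in TruSeq.

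**Figure D2:**
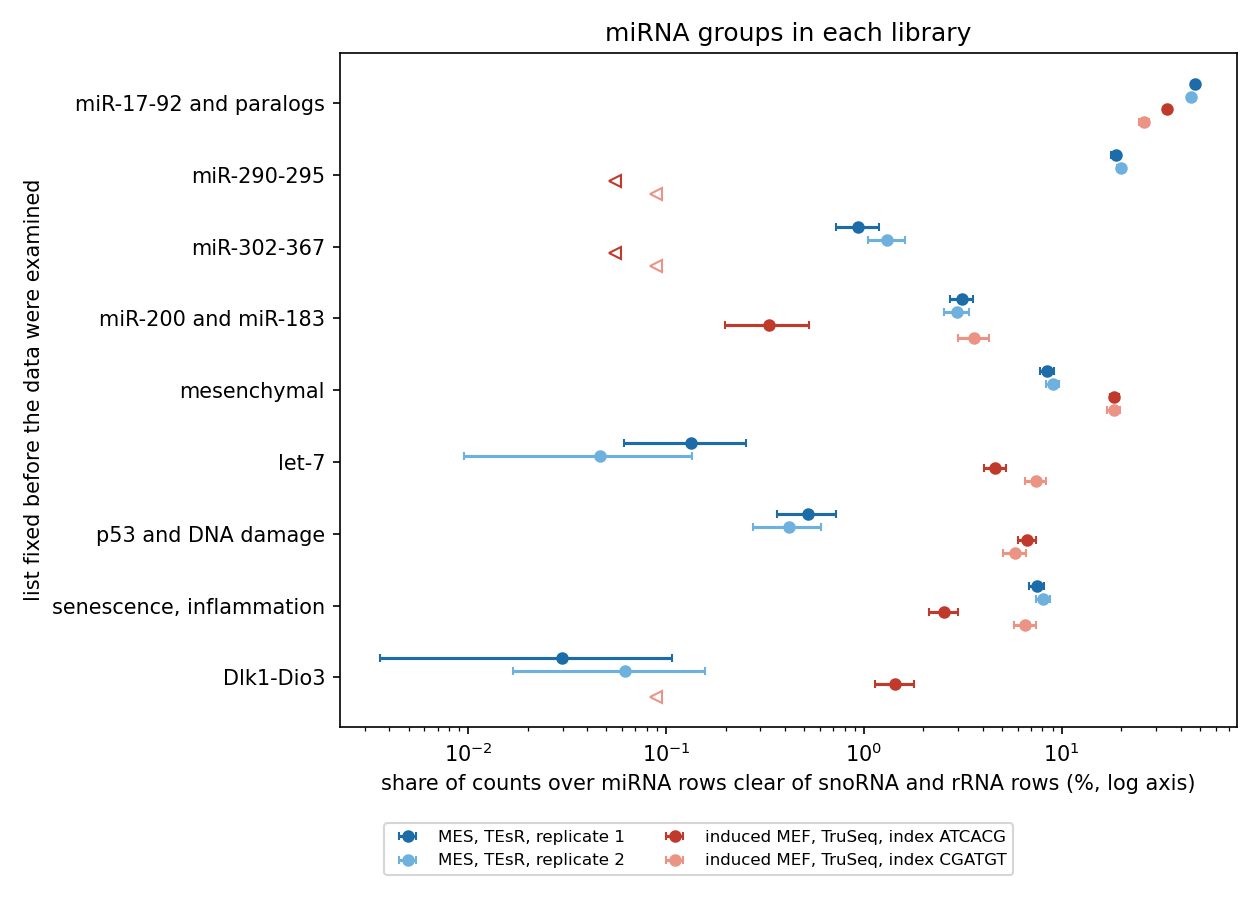
Share (%, log axis) of the counts over miRNA rows clear of snoRNA and rRNA rows for 9 groups of miRNAs in each library, with exact 95% binomial intervals for counting error only; open triangles mark the limit of 3 counts where a library had none. The miR-290-295 points lie at 18.7% and 20.03% in MES, with no count in either TruSeq library, while let-7 lies at 4.61% and 7.40% in TruSeq.

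A comparison per RNA was made between the MES TEsR and the induced MEF TruSeq libraries, chosen after seeing the data, in which cell type, library method, instrument and depth all change together among the libraries used here; the MEF TEsR columns were not used here. In MES, 129 of 352 tested rows were higher and 176 lower by edgeR's quasi-likelihood test with a Benjamini-Hochberg adjusted p under 0.05. The miRNAs and the other classes parted: 66 of 96 miRNA rows were higher in MES and 21 lower, 63 of 235 snoRNA rows were higher and 138 lower, and 15 of 19 snRNA rows were lower with 0 higher. These directions are relative to the scaling, which put the median log2 fold change of all rows at -1.06, against -0.65 with DESeq2's size factors and -2.42 with library size only. With library size only, 101 rows were higher and 219 lower, and with miRNAs scaled on their own, 50 were higher and 43 lower of 113.

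Among rows with more than 3 counts in every library, the highest CPM ratios of MES to TruSeq were those of Snord70 (1320-fold) and Gm26293 (1272-fold), both of Nop58, followed by Snord68 (302-fold) and Mir106b (138-fold). The highest ratios the other way were those of Gm23246 of Snhg1 (5404-fold) and AC161199.1 (1507-fold). These rows were chosen after their values were seen. The fixed rule ranks fitted fold changes, which favours rows with no count in one group. The 8 rows it took as higher in MES were miRNA rows without a TruSeq count, so that their folds are lower bounds against 3 counts per library on the CPM scale and set no order against the rows above. Mir19a, of the miR-17-92 cluster, was at least 633-fold higher in MES, at 219 ± 5.78 (SD, n = 2) CPM. Mir292, which shares its counts with the overlapping row mmu-mir-292b, was at least 597-fold higher, Mir291a at least 280-fold, Mir295 at least 278-fold and Mir294 at least 100-fold, all of the miR-290-295 cluster. Mir672, in an intron of Nexmif, was at least 172-fold higher and Mir205 at least 161-fold. The 8 rows it took as lower had no MES count, and all but Snord88c and Gm22059 were snRNAs. Gm25099 was at least 3610-fold lower in MES, Rnu5g at least 486-fold, Gm24871 at least 344-fold, Gm23287 at least 331-fold, Rnu7, the U7 RNA of histone mRNA processing, at least 258-fold and Gm23143 at least 117-fold. The snoRNAs Snord88c and Gm22059 were at least 127-fold and 81.6-fold lower. Copies of snRNA genes are near-identical, so the split of reads between the snRNA rows is uncertain. The tag q10 stands in the TEsR column names only, and whether both tables were filtered alike is not stated. A difference in processing therefore cannot be told apart from a lower level for snRNA rows without a MES count, and this was not tested. The same limit holds for miRNA rows that have a further gene copy and few or no MES counts. Among them are Mir19b-1, Mir92-1, Mir16-1, mmu-let-7f-1, Mirlet7c-2 and Mir199a-2.

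By fixed list, all 9 tested rows of the miR-290-295 cluster (7 with duplicates counted once) were higher in MES over all rows and adjusted over the list alone (limma camera, adjusted p = 2.36e-04, and adjusted p = 0.485 with an estimated correlation). Of 11 tested members of miR-17-92 and its paralogs, 9 were higher and 2, Mir19b-1 and Mir92-1, lower, also adjusted over the list alone (camera, adjusted p = 0.00586, and adjusted p = 0.485 with an estimated correlation). With miRNAs scaled on their own, this list did not pass (adjusted p = 0.194). Mir106b was higher by a log2 fold change of 8.47 ± 0.23 (SE; edgeR adjusted p = 5.51e-08), Mir20b at least 68.8-fold and Mir106a at least 35.1-fold, while Mir19b-1 was lower (log2 fold change -7.19 ± 0.94, SE; edgeR adjusted p = 1.59e-04). Mir93, also called higher, turned to -0.095 with miRNAs scaled on their own. No other list passed camera at an adjusted p under 0.05. All 4 tested members of the miR-200 and miR-183 families were higher, Mir200c at least 79.6-fold and Mir200b at least 22.2-fold, though Mir183 turned to -0.35 with miRNAs scaled on their own (camera, adjusted p = 0.0814). Of the let-7 family, 4 of 6 were lower and 0 higher, and 2 lower adjusted over the list alone (camera, adjusted p = 0.174). On the CPM scale, mmu-let-7f-1 and Mirlet7c-2 were at least 4.37-fold and 3.94-fold lower. These bounds would be smaller with the scaling that the calls use. With miRNAs scaled on their own, the let-7 list passed (camera, adjusted p = 0.0121). With an estimated correlation over all rows it did not (camera, adjusted p = 0.609), nor did any other list.

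Of 10 tested mesenchymal miRNAs, 5 were higher in MES and 3 lower, among them Mir29b-1 (log2 fold change 7.35 ± 0.41, SE) and Mir21a (5.51 ± 0.30, SE), which were higher, and Mir199a-2, which was at least 11.8-fold lower (camera, adjusted p = 0.455). Of 4 senescence and inflammation miRNAs 3 were higher and 0 lower (adjusted p = 0.156), including Mir29b-2 (log2 fold change 5.0 ± 0.69, SE). Of 4 p53 and DNA damage miRNAs, Mir34a was higher (log2 fold change 5.01 ± 0.56, SE) and Mir16-1 at least 4.88-fold lower, while the other two were not called (adjusted p = 0.821); the median and mean of this list lay below 0 and the camera direction was up. In the lists with fewer than 3 tested members, Mir302a was at least 59.6-fold, Mir302b at least 11.2-fold and Mir467c at least 44.6-fold higher. Scarna10 and Scarna9, RNAs of Cajal bodies, were lower, the first by at least 19.2-fold and the second by a log2 fold change of -3.70 ± 0.50 (SE). Of the imprinted snoRNAs Snord107 (log2 fold change 2.84 ± 0.34, SE) and Snord64 (1.14 ± 0.25, SE) were higher relative to the scaling, and Snord64 turned to -0.22 with library size only.

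Among the guide RNAs, 33 of 79 tested C/D box snoRNA rows were higher in MES and 36 lower, or 32 and 36 of 78 with duplicates counted once (camera, adjusted p = 0.817; the median and mean of the list were below 0 and the camera direction was up). The list holds rows matched by name, so snoRNA rows named otherwise, such as Gm23212, Gm23246 and Gm26202, are not on it. Over all 235 tested snoRNA rows, 63 were higher and 138 lower, a less even split than that of this list. Snord70 was higher by a log2 fold change of 11.74 ± 0.26 (SE) and Snord68 by 9.62 ± 0.28 (SE), while Snord1a was lower (-9.53 ± 0.49, SE). Of 37 rows of H/ACA box snoRNAs, which guide pseudouridylation, 23 were lower and 6 higher, or 22 and 6 of 36 with duplicates counted once (camera, adjusted p = 0.0869). Among the 6 are Snhg7 and Snora43, which overlap by 127 bases with near-equal but not identical counts and were both kept. SNORA50 was at least 75.6-fold lower, Snora52 at least 32.2-fold and Snora47 at least 16.6-fold. An exception was Snora21 (chr 11, 97781639 to 97781775, in an intron of Rpl23), at 9225 ± 1030 (SD, n = 2) CPM in MES and 67.3 ± 11.2 (SD, n = 2) in TruSeq. The 3 tested spliceosomal snRNAs were lower (camera, adjusted p = 0.155): Rnu5g, Rnu11 by at least 47.5-fold, and Rnu12 (log2 fold change -6.39 ± 0.52, SE). Of the 4 rows of housekeeping RNAs tested, Rnu3a and U3 overlap with identical counts, which leaves 3 RNAs. Rnu7 and Rnu3a were lower and Rnu73b was higher (log2 fold change 2.14 ± 0.29, SE; camera, adjusted p = 0.605). Rnu73b is typed as snoRNA and is on this list only because its name begins with Rnu7, so its rise does not speak for the housekeeping RNAs. Of the names on the list, 8 matched no row. Rnu3a, the U3 snoRNA, had 3600 counts in the ATCACG library and 23422 in the CGATGT library.

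The small RNAs of Gas5 went in opposite directions. Gm23212, of 60 nt, had 1668 ± 90.9 (SD, n = 2) CPM in MES and 468900 ± 46727 (SD, n = 2) in TruSeq, and Gm22489, of 62 nt, had 132 ± 4.85 (SD, n = 2) and 10241 ± 762 (SD, n = 2). Gm22357, of 83 nt, had 15954 ± 29.8 (SD, n = 2) in MES and 708 ± 115 (SD, n = 2) in TruSeq, and Gm26224, of 80 nt, 17223 ± 2998 (SD, n = 2) and 4601 ± 76.7 (SD, n = 2). On the fixed list of Gas5 and Snhg1 snoRNAs, 2 of 5 tested rows were higher and 3 lower, or 1 of 4 higher with the overlapping rows Snord80 and SNORD77, of identical counts, counted once (camera, adjusted p = 0.969; the median and mean lay below 0 and the camera direction was up). Of the names on this list, 13 matched no row, and rows of these hosts named otherwise, such as Gm23212, Gm22357 and Gm23246, are not on it. The list test thus covers only part of the snoRNAs of these hosts. Snord80 was higher (log2 fold change 2.248 ± 0.16, SE), and Snord78 (-1.73 ± 0.22, SE), Snord22 (-1.52 ± 0.36, SE) and Snord47 (-1.52 ± 0.16, SE) were lower. Gm23212, Gm22489, Gm22357 and Gm26224 were chosen after their values were seen.

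**Figure D3:**
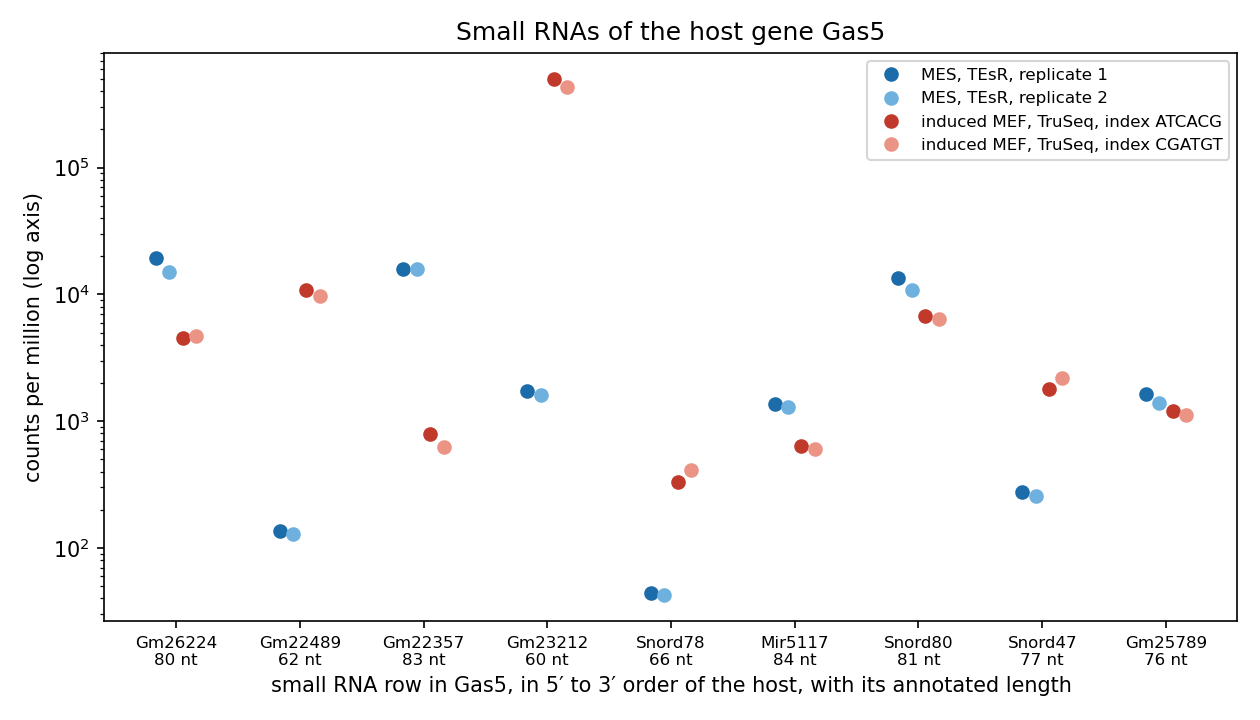
CPM (log axis) of the small RNA rows of Gas5 in each library, in the 5′ to 3′ order of the host gene, with the annotated length of each row in nt; each point is 1 library. Gm23212, of 60 nt, stands at 468900 CPM in TruSeq (mean) and 1668 in MES, while Gm22357, of 83 nt, stands at 708 and 15954.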

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

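All alternatives for the comparison of MES by TEsR with induced MEF by TruSeq, AC161199.1 counted as snoRNA, duplicates counted once, and Mir92-1 left out were chosen after seeing the data; the others were planned. The planned comparisons of MEF groups, and so their alternatives, were not run. No paired analysis was possible because the TruSeq columns carry no replicate number. Where a library is left out, the lone library is assumed to vary like the other group. The cause of the shifts below was not tested, except that leaving a row out or moving it changes the total or the class by construction.

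With the most abundant row of each library left out, miRNAs took 0.682% in MES and 43.2% in TruSeq, snoRNAs 99.3% and 51.9%, and snRNAs 0.00591% and 1.29%. With AC161199.1 counted as snoRNA, miRNAs took 0.300% and 0.110% and snoRNAs 99.7% in MES and 97.3% in TruSeq. With duplicates counted once, miRNAs took 0.282% and snoRNAs 99.7% in MES. Leaving rRNA rows out moved no share by 1 SD, and no detection count over all rows or snoRNAs moved over 1.5 times, nor any in MES. In TruSeq, snRNAs with at least 1 count rose from 29.5 to 47.5 without thinning and rRNAs from 14.5 to 25.5. With at least 10 counts, rRNAs went from 1 to 3.5 without thinning and to 3 with a minimum of 5 counts, and miRNAs from 31.5 to 70 and 51. Clear miRNAs with at least 10 counts in TruSeq, 23.5 after thinning, rose to 55.5 without thinning, the same as in MES, and to 41 with a minimum of 5 counts, against 75 in MES. With Mir92-1 left out, the miR-17-92 list took 19.1% of clear miRNA counts in TruSeq in place of 30.1%.

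In the added comparison, counts of calls stayed within 1.5 times under every alternative run except miRNAs only (50 higher, 43 lower, with fewer rows tested). The number of lists called was 2, but 6 without a filter, 0 with an estimated correlation and 11 by fry, which does not compare a list with other RNAs; leaving out 1 library gave 2 to 4, the 4 without MES replicate 1. The miR-17-92 list had an adjusted p of 0.194 with miRNAs only and 0.485 with an estimated correlation, within a range of 1.08e-06 to 0.485 over the alternatives; miR-290-295 had 0.485 with an estimated correlation, within a range of 5.55e-07 to 0.485. Of the rows on the lists or named, 151 were called; over 11 alternatives they kept sign and call in 1427 instances, lost the call in 100 and reversed in 12. With library size only, the reversed log2 fold changes were Snord100 -0.67, Snord37 -0.70, Snord72 -0.79, Snord110 -0.18, Snord85 -0.68, Snord99 -0.54, Snord64 -0.22, Snord15b -0.48 and Snord14d -0.37. With miRNAs only, they were Mir93 -0.095, Mir183 -0.35 and Mir27b -0.20.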

Other observations

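The tests of snoRNA length and GC content, those of the Dlk1-Dio3 locus against yield and as a whole locus, and that of host transcription were chosen only after the result was seen.

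The 2 TruSeq libraries differed at the Dlk1-Dio3 imprinted locus on chr 12, whose maternally expressed transcripts Meg3, Rian and Mirg carry snoRNAs and miRNAs. The 14 snoRNA rows of the locus had 4980 counts in the ATCACG library and 2 in the CGATGT library, against 21 and 21 in MES. Gm23787 (109684962 to 109685034) had 3718 counts against 1, AF357341 had 329 against 0, and AF357428 had 242 against 0. The snoRNAs DQ267100 and AF357425 of Rian had 225 against 0 and 212 against 1. Of the miRNAs, Mir540 had 33 counts against 0, Mir127 12 and Mir341 11 against 0. In all, 16 rows had at least 10 counts in the ATCACG library and at least 20 times fewer counts in the other, and 15 of these lie at the locus; 0 rows did so the other way round. All 15 rows of the locus with at least 10 counts in the ATCACG library were among them, against 1 of 328 rows outside.

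A lower yield or depth in the CGATGT library is argued against: 0 of 10000 random lists of rows matched on their counts had as few counts there, with a median of 5804 and a lowest value of 3786. Cell populations whose miRNAs differ widely cannot be told apart from other causes, since 1 miRNA outside the locus, AC034285.1, had at least 10 counts in one library and none in the other, too few to decide. A candidate explanation is that the whole locus was silent or lost in the cells of the CGATGT library. Its snoRNAs stood there at 0.0426% of their CPM in the other library, but this value restates the pattern and so does not test the explanation. The labels give no group that parts these libraries, so no biological explanation from the design was tested, and a mislabelled sample stays open.

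A second pattern was that snoRNAs of one host could part between the groups. In hosts with at least 4 snoRNAs, the SD within a host of the log2 ratio of MES to TruSeq CPM, which scaling does not move, ran from 1.42 in Eif4a2 to 4.61 in Taf1d. Rian, at 0.70, is left aside here because its TruSeq counts lie in the ATCACG library almost alone. Across the 9 small RNAs of Gas5, the ratio had an SD of 4.10, against 0.217 between replicates, and ran from -8.13 to 4.50. A change in transcription of the host gene, which would move them together, is argued against by this SD as the whole cause at Gas5. Outside Gas5 and Rian, 18 pairs of snoRNAs within one host differed by at most 2 nt. Their median absolute difference in the log2 ratio was 3.13. Between replicates it was 0.372 over all 23 such pairs, Gas5 included. This argues against host transcription as the whole cause for the hosts of these pairs as a set, not host by host. Host transcription as part of the cause stays open, and at Eif4a2, which has no such pair, it stays open altogether. The 4 snoRNAs of Nop58 all stood higher in MES (2.37 to 10.38) and the 8 of Snhg1 all lower (-12.31 to -2.52) on the scale of library size, and these signs held with either other scaling (lowest of Nop58 3.74 and highest of Snhg1 -0.74). In Nop56, Snhg12, Eif4a2 and 2410002F23Rik all stood lower only on the scale of library size. RNA length acting through the library method is argued against as the whole cause, whatever the shape of its trend. In 23 pairs of snoRNAs of one host that differ by at most 2 nt, Rian left out, the median absolute difference in the log2 ratio was 3.28 (quartiles 1.86 and 5.51), against 0.372 between replicates, and 21 pairs differed by more than 1. Without Gas5 the median was 3.13 over 18 pairs. GC content acting through the library method is argued against as the whole cause in the same way: in 22 pairs that differ by at most 2 percentage points of GC the median was 2.89 (quartiles 1.82 and 3.61), against 0.337 between replicates, and 19 pairs differed by more than 1. Pairs of one host share members and are not independent.

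Length or GC content as part of the cause stays open. Spearman's rho of length with the ratio over 235 snoRNA rows was -0.068 (permutation p = 0.295, adjusted p = 0.443), and Pearson's r was -0.149 (unadjusted permutation p = 0.0194). For GC content rho was -0.069 (permutation p = 0.292, adjusted p = 0.443) and Pearson's r -0.116 (unadjusted permutation p = 0.0750). None of these decides, since such a value also arises from a trend that rises and falls. Over 17 rows of Gas5 and Snhg1, each centred on its host, rho was 0.649 (permutation p = 0.00638, adjusted p = 0.0191; Pearson's r = 0.474, and 0.618 without the 2 extremes). This rests on Gas5, the host that drew attention, with a rho of 0.90 over 9 rows against -0.012 over 8 rows of Snhg1.

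Over the 137 snoRNA rows of 100 nt or less, rho of length with the ratio was 0.327 (permutation p = 1.40e-04, adjusted p = 8.40e-04). By length, the median log2 ratio was -5.37 up to 65 nt, -3.33 at 66 to 70 nt, -2.30 at 71 to 75 nt, -2.88 at 76 to 80 nt, -0.79 at 81 to 85 nt, 0.43 at 86 to 90 nt, 0.16 at 91 to 100 nt and -3.96 above 100 nt. The SD within these bins ran from 2.60 to 5.74, and 4 of the bins hold under 20 rows. Rows above 100 nt include H/ACA box snoRNAs such as Snora44, of 129 nt, and Snora81, of 178 nt. Length and snoRNA class are therefore not told apart in that bin. The correlations, adjusted over 6 of them, are across RNAs, which are not independent replicates. Cell type, which the design names, stays open and untested. Among the libraries used here it changes together with the method and with induction, since the 4 MEF columns made by TEsR were not used.

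Snord33 and mmu-mir-5121, which overlap by 30 bases in Rpl13a, shared their counts differently. The mmu-mir-5121 row had 98.5% and 99.1% of the count of Snord33 in the MES libraries, and 2.44% and 3.63% in the TruSeq libraries. Mir19b-1 and Mir92-1, neighbours that do not overlap, had 859 and 859 counts in the ATCACG library and 391 and 389 in the CGATGT library.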
